A study of Rattus norvegicus with 13 samples.

How the data were processed

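H3K4me2 was profiled by CUT&Tag in control, Myocd-LSD1 and Myocd-LSD1NF rat aortic SMC lines (3 samples each) and FLAG in FLAG-tagged Myocd-LSD1 cells (4 samples), 13 samples in 4 groups, per the labels. Cells were bound to concanavalin A beads, incubated with an H3K4me2 or FLAG antibody and then with pA-Tn5, per the labels' protocols. Bowtie2, deepTools, MACS2, ChIPseeker and DiffBind and the rat build rn6 are named, without versions, roles or settings, per the submitters' processing notes. Tn5 offsets, duplicate removal and scaling between libraries are not given in the sources used here.

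The authors deposited a peak list per group in the columns MACS2 and ChIPseeker write, per the file headers. All peak names in a list carry a single alignment name, and whether replicates were pooled before calling is not stated. The deposited score is 10 times the -log10 q-value without its decimals, as the values show. The deposited fold is the fold enrichment of a peak over its background, taken from the fold change column per the file headers. The authors' -log10 p-value and -log10 q-value columns come from peak calling, and all listed peaks have a q-value under 0.05. A peak called in a single list can differ from others by depth alone. The authors' deposited table of the DiffBind comparison gives, per the file headers, a mean log2 concentration per line, their log2 difference, a p-value and an FDR. The sign was read from the values: the deposited fold equals the Myocd-LSD1 minus the Myocd-LSD1NF concentration within 0.01. The lowest values in the log2 concentration columns of the authors' deposited table, -0.08 and -0.11, are floors for sites with almost no reads. The test used inside DiffBind and its normalization are not stated. Depth per sample is unknown.

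From these files, overlaps of at least 1 bp were counted between lists and sites, with start positions turned to 1-based counting. Expected overlap came from 1000 random offsets per chromosome, on autosomes and X, and from offsets of 10 to 100 kb. Sites were given to the nearest TSS among all transcripts named in the lists; on 3000 peaks of each list this gave the authors' gene in 98.9% to 99.5% of cases and the authors' distance in 100%. A promoter is the region within 3 kb of a TSS. For gained and lost promoter peaks, a gene counted as marked when a peak lay within 3 kb of any of its TSSs. This reading was settled after a first pass with the annotated gene, which gave false switches where a peak lies between 2 genes. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

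Gene lists were fixed before the data were examined: 17 lists with 473 entries, of which 406 matched a gene name in the lists, 8 through a synonym in the RefSeq table of GRCr8, used for names only. Two-sided Fisher's exact tests compared list members with all 19345 genes that had an H3K4me2 peak in either line, or, for FLAG, with the 21397 genes named in any list, with Benjamini-Hochberg adjustment. As an alternative, 10000 random sets of genes with like numbers of H3K4me2 peaks in those lines served as background. Genes named in the text followed a rule fixed before the data were examined. It takes the 10 sites with the largest difference in each direction with a gene symbol, the SMC contractile and SMC regulator genes with a site, and up to 4 genes of any other list that passed. It also takes the 10 highest FLAG peaks, the contractile and regulator genes with a FLAG peak, the 10 genes with the highest promoter peaks among those absent or present only in Myocd-LSD1, and Acta2, Myh11, Tagln, Cnn1, Myocd and Kdm1a. Only the highest of the contractile and regulator FLAG peaks are printed. Genes named outside the rule were chosen after their values were seen. They are the matrix genes Fbn1, Eln and Loxl1 and the genes in the closing section that the report does not name elsewhere. Some genes that the rule takes are not used here.

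Alternatives changed the promoter distance, the overlap, the top 50% of each list by q-value, list length, the FDR, the size of the difference, the background and the assignment of sites. The overlap code recovered 100% of planted overlaps in simulated lists. In 200 simulated lists of 18 genes out of 19345, Fisher's exact test called 3.0% of random lists, 25.5% of random lists rich in peaks and 100% of lists with 50% of members planted; matching on peak number called 6.0% of 100 lists rich in peaks. The direction test against matched genes called 2.0% of 100 lists of 14 genes with random directions. Shifts called 2.5% of 40 randomly moved lists. Sequences outside autosomes and X were left out of the shift test and the named genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with plots by matplotlib 3.10.9.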

Results

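CUT&Tag was used to map the histone mark H3K4me2 in 3 rat aortic smooth muscle cell (SMC) lines and the FLAG epitope in a line carrying a FLAG-tagged fusion. In CUT&Tag an antibody tethers the Tn5 transposase to chromatin, so that DNA next to the bound epitope is cut and sequenced. H3K4me2, dimethylated lysine 4 of histone H3, marks active and poised promoters and enhancers, and LSD1 (gene Kdm1a) is a demethylase that removes it. Myocd encodes myocardin, the coactivator of serum response factor that drives contractile genes in SMC. The H3K4me2 samples came from control, Myocd-LSD1 and Myocd-LSD1NF cells (n = 3 samples each), and the FLAG samples from FLAG-tagged Myocd-LSD1 cells (n = 4). The labels do not spell out what NF stands for, and nothing in them says whether the samples of a group were separate cultures. Each group had a single peak list, so comparisons of lists have no replicate error, and read depth per sample was unknown. Only the comparison of Myocd-LSD1 with Myocd-LSD1NF had a table made from replicates.

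The first comparison asked where the mark was called in each line. H3K4me2 peaks numbered 42672 in control, 42405 in Myocd-LSD1 and 42727 in Myocd-LSD1NF cells. Promoters, meaning positions within 3 kb of a transcription start site (TSS), held 45.8% of control peaks (95% interval 45.3 to 46.2), 44.6% of Myocd-LSD1 peaks (44.2 to 45.1) and 42.5% of Myocd-LSD1NF peaks (42.0 to 43.0). Introns held 25.6%, 25.9% and 27.3% of the peaks of these lists, and distal intergenic sequence 23.3%, 23.8% and 24.6%. The intervals are exact binomial intervals that cover counting error only, and the order of the lists was not tested. Among SMC contractile genes, Acta2 (smooth muscle actin) and Tagln (transgelin) carried promoter peaks in all 3 lists, as did Cnn1 (calponin). Myh11, which encodes the smooth muscle myosin heavy chain, had a promoter peak in control (chromosome 10, 778919 to 779279, rn6) and in Myocd-LSD1NF cells (778723 to 779392) and no peak in Myocd-LSD1 cells. Both Myh11 peaks were low, with a fold enrichment of 4.71 and 4.65 in their own lists. Kdm1a had promoter peaks in all 3 lists. Scores and fold enrichments of peaks are the authors' values and are used only within a list.

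Most H3K4me2 peaks were shared between lines. Of the control peaks, 71.8% overlapped a peak in both other lists, 9.0% only in Myocd-LSD1NF, 7.0% only in Myocd-LSD1, and 12.1% in neither. Pairwise, 78.9% of control peaks (78.5 to 79.3) overlapped a Myocd-LSD1 peak and 80.8% (80.4 to 81.2) a Myocd-LSD1NF peak, while 78.2% of Myocd-LSD1 peaks (77.8 to 78.6) overlapped a Myocd-LSD1NF peak. Moving the peaks of each chromosome by a random offset left 2.33% overlap for control on Myocd-LSD1, 2.34% for control on Myocd-LSD1NF and 2.45% for Myocd-LSD1 on Myocd-LSD1NF. Offsets of 10 to 100 kb, an expectation chosen after seeing the data, left 5.49%, 5.56% and 5.84% (permutation p = 0.001 for each random-offset test, the smallest 1000 shifts can give). Myocd has TSSs at 51778986, 51781452 and 51781458 on chromosome 10, of which the first lies farthest downstream. The control list had a promoter peak across that TSS (51778566 to 51780365). Myocd-LSD1NF cells had 3 promoter peaks between 51777211 and 51780367, where Myocd-LSD1 cells had none. The only Myocd-LSD1 promoter peak lay farther upstream (51783353 to 51784049), at -1895 bp from a TSS, where the other H3K4me2 lists had no peak. At Cnn1 the peak on the TSS in control (chromosome 8, 23112734 to 23113254) and Myocd-LSD1NF cells (23112821 to 23113277) had no counterpart in Myocd-LSD1 cells, which kept a narrower peak inside the gene (23113796 to 23114431).

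**Figure D1:**
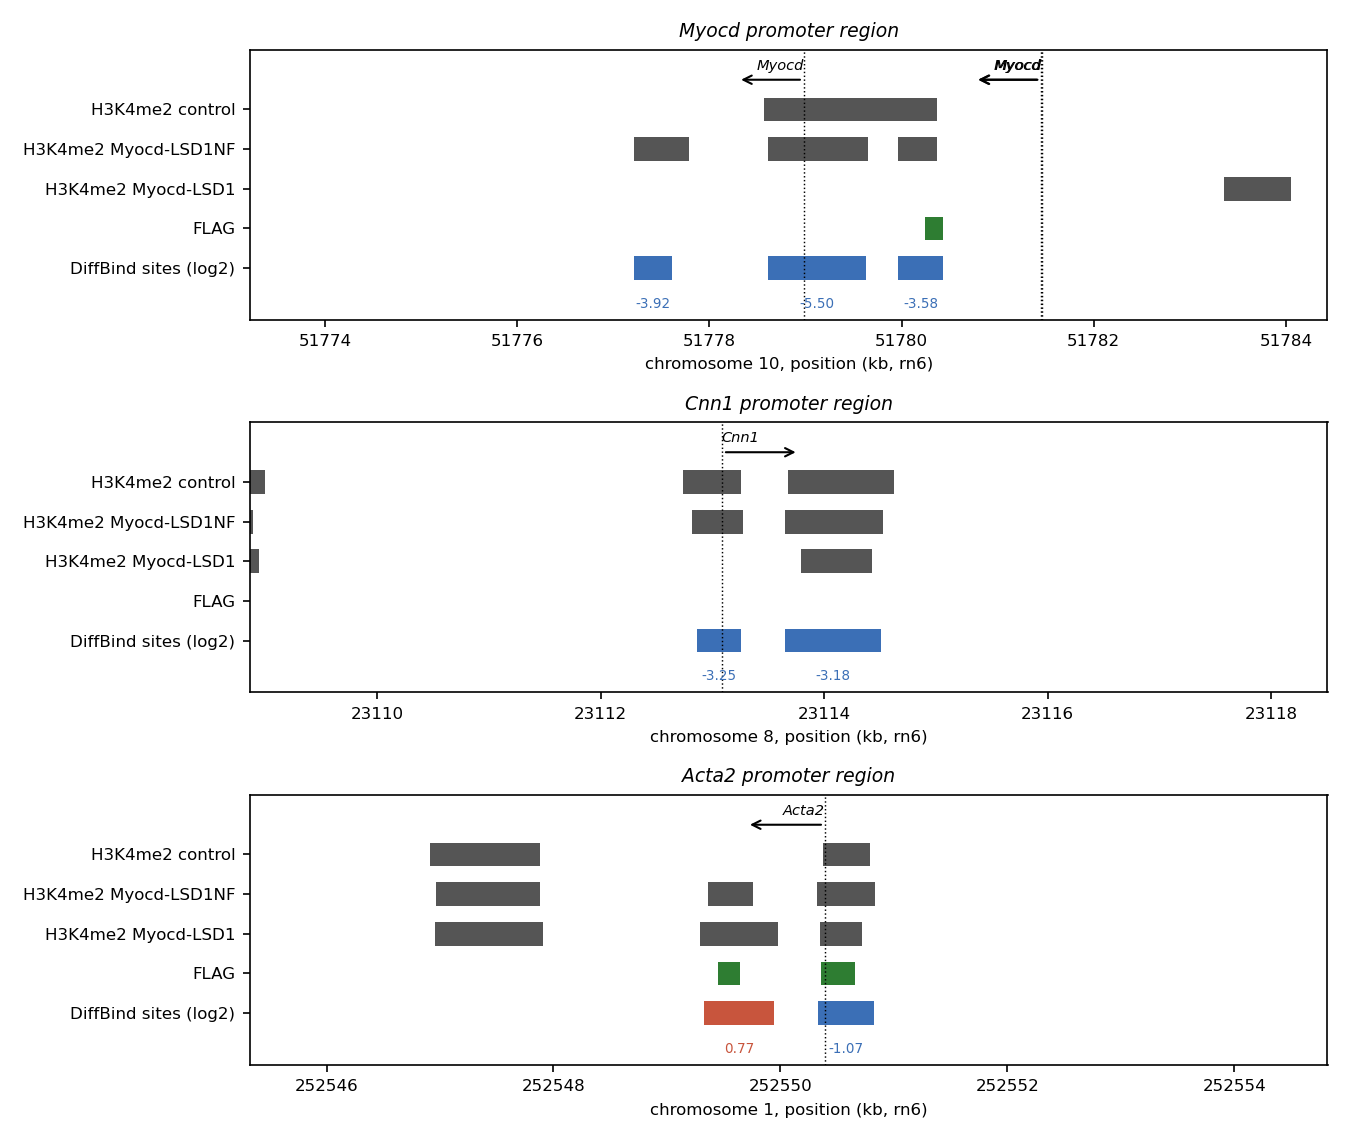
Peaks of the 4 lists (grey H3K4me2, green FLAG) and sites of the authors' deposited table (blue lower, red higher in Myocd-LSD1, with the log2 difference) around the promoters of Myocd, Cnn1 and Acta2; the x axis is the rn6 position in kb, dotted lines are TSSs and arrows the direction of transcription. The 3 Myocd sites shown differ by -3.92, -5.50 and -3.58, the Cnn1 sites by -3.25 and -3.18, and the Acta2 sites by -1.07 at the TSS and 0.77 inside the gene.

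Promoter peaks were then compared gene by gene. A peak within 3 kb of a TSS was present in all 3 H3K4me2 lists at 13276 genes. It was absent only in Myocd-LSD1 at 293 genes, absent only in Myocd-LSD1NF at 653 and absent only in control at 199; it was present only in Myocd-LSD1 at 352, only in Myocd-LSD1NF at 221 and only in control at 623. Among the genes without a promoter peak only in Myocd-LSD1 were the contractile gene Myh11 and the vascular channel gene Kcnj8. Those with the highest control peaks were Ehhadh (fold enrichment 15.4), Actl10 (10.3), NEWGENE_1562258 (8.19), Kcnj8 (12), Tbc1d2 (10.2), LOC108351372 (9.91), Cmya5 (14.5), Pla2r1 (13.7) and Isyna1 (9.45). Genes with a promoter peak only in Myocd-LSD1 were led by LOC100910069 (14.4), Myom2 (8.98), Kcna6 (10.5), LOC102548611 (13.9), Lrfn5 (14.1), Pabpc4l (14.3), Sostdc1 (14.2), LOC100912683 (12.7), Dpp6 (9.51) and LOC100910518 (6.99).

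Presence in a list and the replicate test often differed for the same gene. Of the 293 genes without a promoter peak only in Myocd-LSD1, 82 (28.0%) had a promoter site that was lower in Myocd-LSD1 in the authors' deposited table. Of the 653 genes without it only in Myocd-LSD1NF, 255 (39.1%) had a promoter site that was higher in Myocd-LSD1 in the authors' deposited table. A higher promoter site was found at 71 (20.2%) of the 352 genes with a promoter peak only in Myocd-LSD1. A lower one was found at 18 (8.1%) of the 221 genes with a promoter peak only in Myocd-LSD1NF. In the authors' deposited table Kcnj8, Actl10, Cmya5 and Isyna1 had a lower site, Tbc1d2 3 lower and 1 higher, Myom2 4 and Kcna6 3 higher sites, whereas Ehhadh, Pla2r1 and Myh11 had none. Among the tests of gene lists over these classes, only skeletal and cardiac muscle genes with a promoter peak only in control passed (4 of 7 genes, Acta1, Myh3, Nkx2-5 and Tnni1, where 0.279 were expected; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00813). The authors' deposited table does not cover the control cells, so that list has no replicate check.

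At its downstream TSS, Myocd itself carried far less of the mark in Myocd-LSD1 than in Myocd-LSD1NF cells. In the authors' deposited table the site on its TSS (chromosome 10, 51778613 to 51779624) had a mean log2 concentration of 1.77 in Myocd-LSD1 and 7.27 in Myocd-LSD1NF, a difference of -5.50 (FDR 8.54e-25). Further Myocd sites differed by -3.92 and -3.58 near the TSS and by -3.68 inside the gene in the authors' deposited table. Across the genome the authors' deposited table listed 5183 sites at an FDR of at most 0.05, of which 2174 were lower and 3009 higher in Myocd-LSD1. Their median log2 differences in the authors' deposited table were -2.09 and 2.36, and 1954 lower and 2656 higher sites differed by at least 1. The ratio of FDR to p-value put the number of sites tested at about 36342. The table gives no standard error and holds only sites that passed, so levels per replicate and counts adjusted over a gene list alone were not computed.

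At the largest differences the line with less of the mark had almost no signal. In Myocd-LSD1 cells, sites at Actl10, Pcdh7, Ntrk2, Zkscan4, LOC108348421, Zkscan3 and Kcnd3 were at the lowest value of their column in the authors' deposited table (-0.08), against 6.27 to 7.46 in Myocd-LSD1NF. Il17b, which encodes a cytokine, and Isyna1, which encodes inositol-3-phosphate synthase, were lower by -6.18 (FDR 6.84e-13) and -6.13 (FDR 2.38e-12) in the authors' deposited table. In the other direction Adcy8, an adenylyl cyclase gene, had a TSS site at 8.64 in Myocd-LSD1 and 0.89 in Myocd-LSD1NF, a difference of 7.75 (FDR 1.16e-31), in the authors' deposited table. Sites at F13b, Lmo7, Fbxl17, Paqr3, Tfec, Nek7, Dmrt2, LOC689258 and LOC102546326 were at the lowest Myocd-LSD1NF value of the authors' deposited table (-0.11), against 6.98 to 8.55 in Myocd-LSD1. The lower sites named here all overlapped a control peak. So did the higher sites at Adcy8, Tfec and LOC689258, while the other higher sites named here did not. No fold is given for sites at a column's lowest value, which 233 sites had in Myocd-LSD1 and 454 in Myocd-LSD1NF, because it depends on that floor.

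SMC contractile genes that had a site, 14 of 40, mostly had a lower one in Myocd-LSD1. Of 40 members with an H3K4me2 peak in either line, 12 had a lower site (3.71 expected; two-sided Fisher's exact test, adjusted p = 0.00208 over 34 list tests) and 4 a higher site (5.11 expected; adjusted p = 0.987). Cnn1 was lower by -3.25 (FDR 0.0167) on its TSS and by -3.18 (FDR 1.49e-15) inside the gene in the authors' deposited table. Acta2 differed by -1.07 (FDR 0.00307) at the TSS and by 0.77 (FDR 0.0209) at a site 450 bp inside the gene in the authors' deposited table. TSS sites of Ldb3, Susd5 and Itga8 differed by -1.91, -1.44 and -1.04 in the authors' deposited table, and sites at Ppp1r14a, Lmod1 and Myl9 by -1.17, -1.23 and -2.68. Pdlim7 had 2 lower sites (-1.76 and -2.26), Actn1 3 (-1.73 to -2.41), Filip1l 2 and Cald1 3 lower sites and a higher site (1.65) in the authors' deposited table. Synpo2 (1.22) and Mylk (1.75), the gene of myosin light chain kinase, had only a higher site in the authors' deposited table, and Tagln and Myh11 had none. Contractile genes hold many peaks, and against genes with as many peaks 7.55 members would have a lower site (permutation p = 0.0968, adjusted p = 0.573).

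SMC regulators were split between the directions. Of 29 members, 10 had a lower site (2.69 expected; two-sided Fisher's exact test, adjusted p = 0.00208) and 7 a higher site (3.71 expected; adjusted p = 0.380); against genes with as many peaks the first call ended (6.30 expected; permutation p = 0.142, adjusted p = 0.573). With sites within 3 kb of a TSS only, 3 regulators had a lower site (Fisher's exact test, adjusted p = 0.141). Beside Myocd, the lower sites in the authors' deposited table were nearest to Mef2c (-2.56), Hey2 (-2.12), Smad3 (-0.88 to -2.49), Mkl2 (-1.16 and -0.70), Foxc1 (-1.04), Tead3 (-0.84), Prrx1 (-0.70) and Mir143 (-0.65). Tead1 had 2 lower sites (-3.45 and -0.96) and a higher site (2.20) in the authors' deposited table. Higher sites in the authors' deposited table were nearest to Klf4 (4.02), a factor linked to SMC dedifferentiation, and to Tgfbr2 (3.30), Tcf21 (2.85), Jag1 (1.23), Foxc2 (1.15) and Mef2d (0.61). Some of these sites lie far upstream of the TSS, at -93241 bp for Klf4, where control cells had no peak, and at -253860 bp for Hey2. Kdm1a had no site in the authors' deposited table.

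Osteogenic and chondrogenic genes mostly had higher sites in Myocd-LSD1. Of 18 members, 10 had a higher site where 2.30 were expected (two-sided Fisher's exact test, adjusted p = 6.38e-04), and 3.11 were expected among genes with as many peaks (permutation p = 6.00e-04, adjusted p = 0.0204). All 10 had such a site within 3 kb of a TSS. The chondrocyte factor gene Sox9 stood at 6.76 in Myocd-LSD1 and 3.31 in Myocd-LSD1NF, a difference of 3.45 (FDR 2.46e-14), in the authors' deposited table. Its partner gene Sox6 was at the lowest Myocd-LSD1NF value of the authors' deposited table, against 3.74 in Myocd-LSD1. Sox5 had 3 higher sites, with differences of 5.40 and 3.44 at those off the floor, and Runx2, the osteoblast factor gene, had 3 higher sites and a lower one (-1.80) in the authors' deposited table. Of the 16 higher sites of this group, 10 overlapped a peak of the control list, 5 of them with no Myocd-LSD1NF peak, and 5 overlapped a FLAG peak.

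Extracellular matrix genes differed in both directions. Of 36 members, 10 had a lower site (3.34 expected; two-sided Fisher's exact test, adjusted p = 0.0104) and 8 a higher site (4.60 expected; adjusted p = 0.380); against genes with as many peaks the first call ended (6.85 expected; permutation p = 0.240, adjusted p = 0.799). The 4 genes with the largest differences in size in the authors' deposited table were Fbln5, Mmp2, Spp1 and Col6a3. Fbln5 had lower sites (-4.66 and -3.59) beside a higher site at 1.80 in the authors' deposited table. Mmp2, Spp1 and Col6a3 each had a higher site at the lowest Myocd-LSD1NF value. Among lower sites alone, the next genes in the authors' deposited table were Fbn1 (-2.57 and -1.41), Eln (-1.05 to -2.51) and Loxl1 (-2.28 and -1.09). None of the other lists passed in either direction (Fisher's exact tests, adjusted p from 0.109 to 1). Their counts of lower and higher members were 3 and 1 of 14 for immediate early targets of serum response factor, 6 and 4 of 23 for vascular channels and receptors, 1 and 2 of 15 for endothelial, 3 and 1 of 13 for macrophage and leukocyte, and 1 and 2 of 10 for pluripotency genes. They were 1 and 3 of 16 for fibroblast and adventitial, 0 and 3 of 13 for skeletal and cardiac muscle, 3 and 5 of 16 for neural and neural crest, and 6 and 7 of 32 for HOX genes. They were 4 and 5 of 34 for cell cycle, 1 and 1 of 24 for housekeeping, 1 and 0 of 21 for H3K4 methylation machinery, and 1 and 2 of 23 for inflammatory genes.

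**Figure D2:**
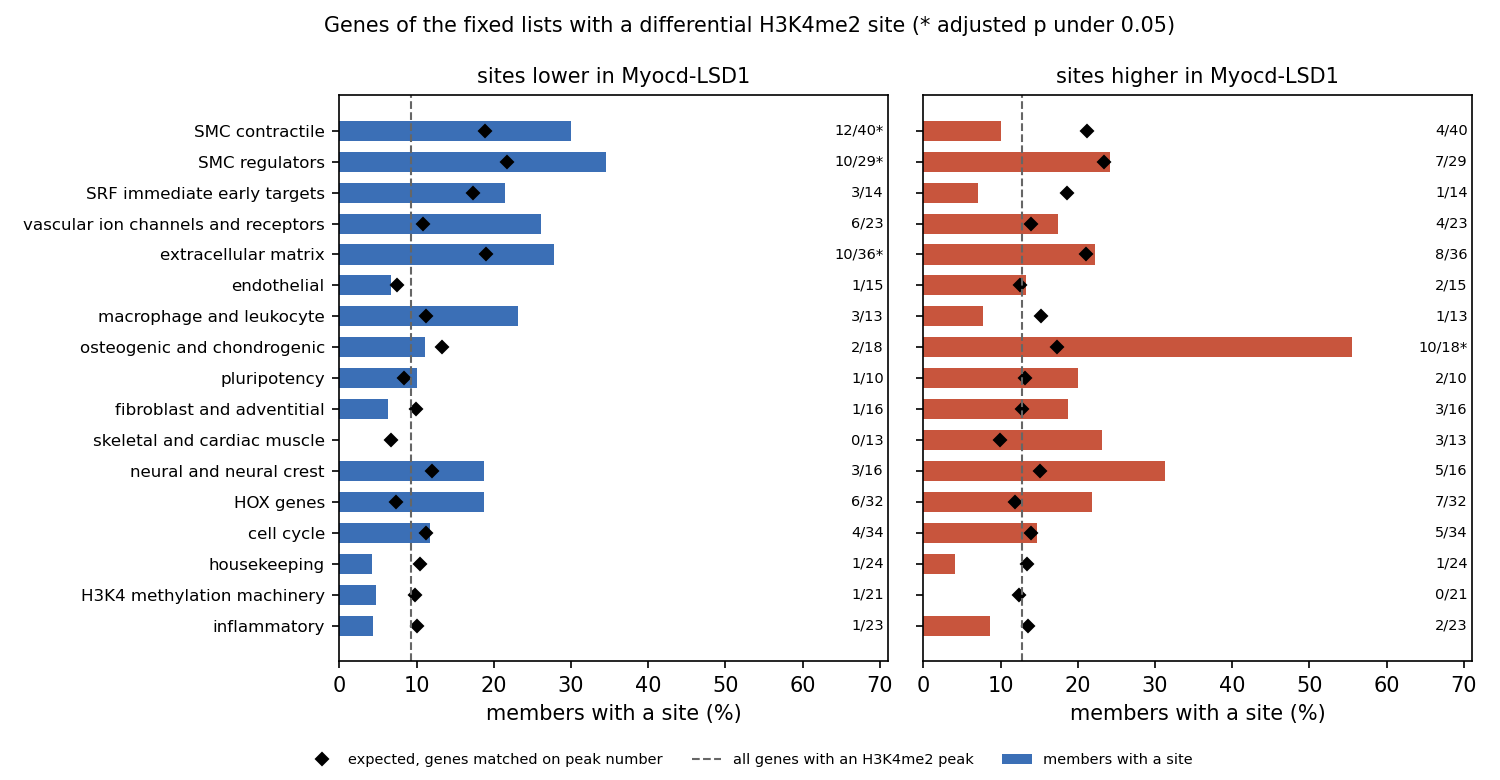
Share of genes of each fixed list with a site lower (left) or higher (right) in Myocd-LSD1; the x axis is percent of members with an H3K4me2 peak, the dashed line the share among all such genes and diamonds the share expected from genes with as many peaks. Osteogenic and chondrogenic genes reach 55.6% on the right, and SMC contractile genes 30% on the left.

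The direction of single sites was tested as a further comparison, chosen after seeing the data. SMC contractile genes held 19 lower and 4 higher sites, SMC regulators 17 and 7, and osteogenic and chondrogenic genes 2 and 16, against 41.9% lower sites in the whole table (two-sided Fisher's exact tests over sites, adjusted p = 0.00238, 0.0419 and 0.0419 over 17 lists). Extracellular matrix genes held 15 lower and 10 higher sites (Fisher's exact test, adjusted p = 0.301). Sites of a gene are not independent; over genes with sites in a single direction, contractile genes were 10 lower and 2 higher (Fisher's exact p = 0.00523, adjusted p = 0.0889) and osteogenic and chondrogenic genes 0 and 8 (p = 0.0245, adjusted p = 0.208), so these calls do not survive the count by gene.

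**Figure D3:**
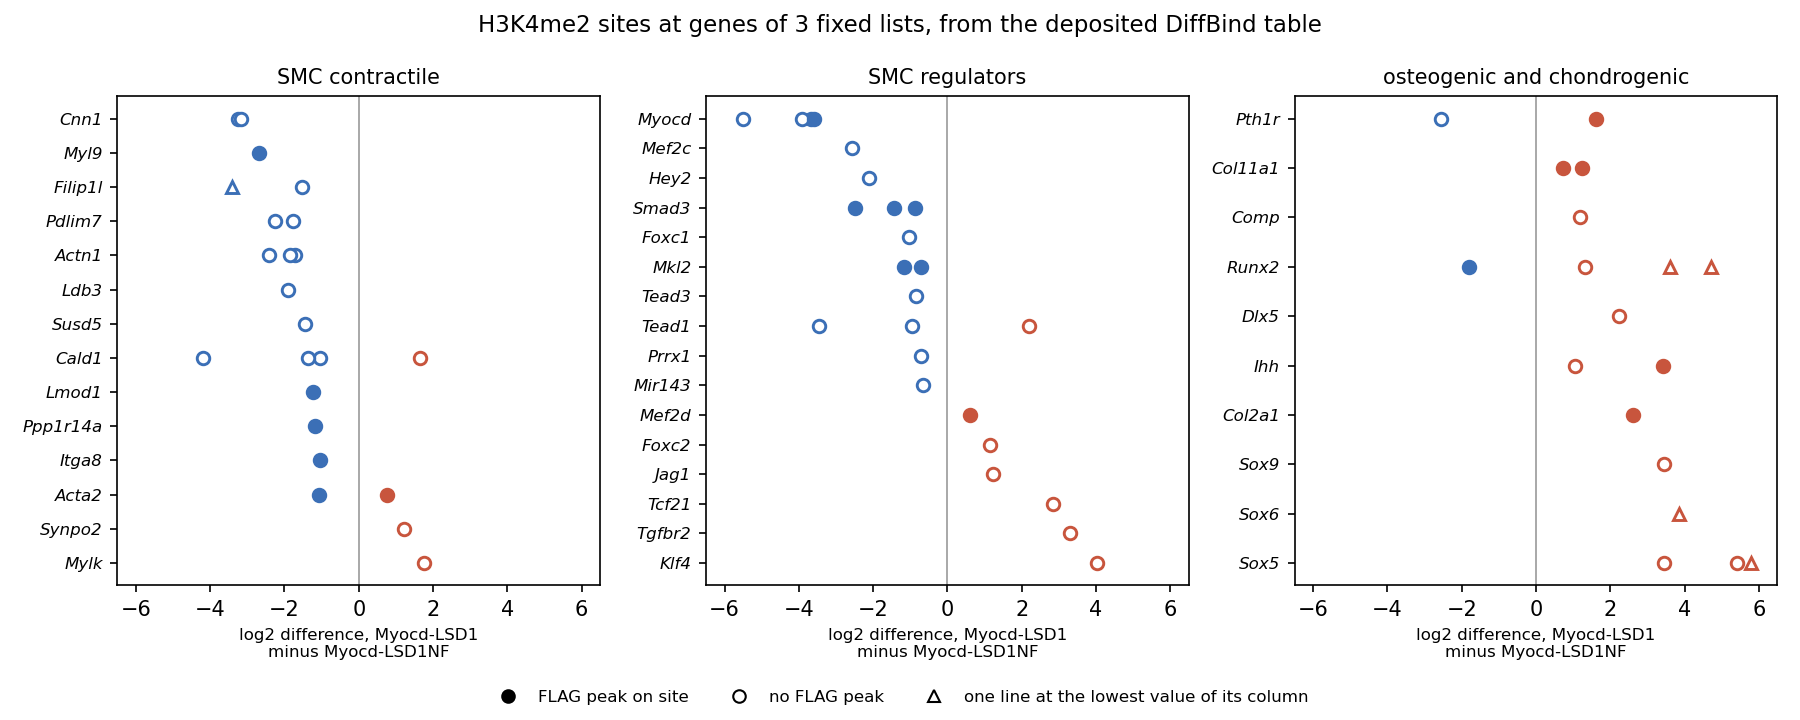
Each point is a site of the authors' deposited table at a gene of 3 fixed lists, shown as the log2 difference between Myocd-LSD1 and Myocd-LSD1NF (x axis); filled points overlap a FLAG peak and triangles have a line at the lowest value of its column. Contractile sites run from -4.19 to 1.75, and 19 of 23 lie below 0, while 16 of 18 osteogenic and chondrogenic sites lie above it.

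Lower sites were mostly ones the control cells also marked. A control peak overlapped 83.8% of lower sites (95% interval 82.1 to 85.3) and 69.2% of higher sites (67.5 to 70.8; two-sided Fisher's exact test over sites, p = 2.72e-34). For scale, 78.1% of all Myocd-LSD1NF peaks and 76.8% of all Myocd-LSD1 peaks overlapped a control peak. At 34.5% of lower sites, Cnn1 and Myocd TSS sites among them, control cells had a peak and Myocd-LSD1 cells none. Control cells had a peak and Myocd-LSD1NF cells none at 25.5% of higher sites, and neither had one at 27.8%. Promoters held 23.0% of lower sites (21.2 to 24.8) and 43.7% of higher sites (41.9 to 45.5; Fisher's exact p = 5.63e-55). With the 50% of control peaks that had the strongest q-values the control peak shares were 43.9% and 41.9% (Fisher's exact p = 0.147), which ends that call. Sites are not independent replicates, and these contrasts were chosen after seeing the data.

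**Figure D4:**
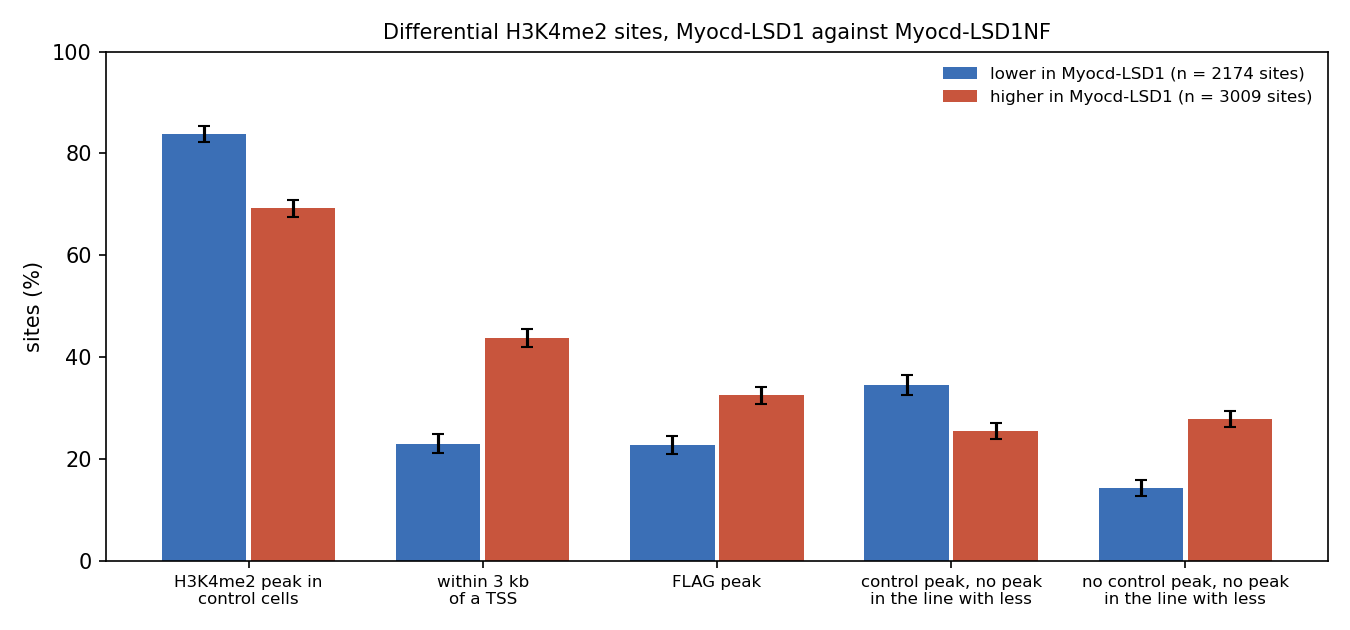
Bars give the percent of the 2174 lower and 3009 higher sites (y axis) that overlap a control peak, a promoter or a FLAG peak, or that lack a peak in the line with less signal; error bars are exact 95% binomial intervals. A FLAG peak lies on 22.7% of lower and 32.5% of higher sites.

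FLAG peaks, called with an antibody against the tag, numbered 26480 and lay at promoters in 40.1% of cases (39.5 to 40.7). Acta2 had 2 FLAG peaks, on its TSS (chromosome 1, 252550354 to 252550659, fold enrichment 7.66) and inside the gene (252549449 to 252549640). Tagln (5.23), Myocd (4.89) and Kdm1a (6.30) each had a FLAG peak within 3 kb of a TSS, and Cnn1 and Myh11 had none. Of 40 contractile genes, 35 had a FLAG peak, 25 of them within 3 kb of a TSS; by score the highest were at the promoters of Dstn (14), Vcl (12) and Tpm2 (7.52) and in introns of Actn1 (7.36) and Pgm5 (7.78). Among regulators 26 of 30 had a FLAG peak, with Tgfbr1 (9.21), Tgfbr2 (8.91), Mkl1 (8.78) and Tead3 (5.76) highest by score, and Srf itself had one 3250 bp inside the gene (6.35). The 10 highest FLAG peaks of all lay in distal intergenic sequence, nearest to Fam13c, Gucy1a2, LOC108351116, LOC108353042, Mucl1, LOC102554462, Gpr89b, Shcbp1, Nwd2 and Papd7, and 9 of them overlapped a peak in every H3K4me2 list. Their -log10 q-values ran from 535 to 1345, against a median of 4.59 over the FLAG list. Whether these peaks depend on the tag was not tested.

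HOX genes carried FLAG less often than other genes. Of 34 HOX genes, 12 had a FLAG peak where 24.0 were expected (two-sided Fisher's exact test, adjusted p = 4.67e-04 over 17 lists; permutation against genes with as many H3K4me2 peaks, adjusted p = 0.00340). HOX genes lie side by side in clusters, whereas both tests take genes as independent, so these p-values overstate the evidence. Cell cycle genes had one more often (33 of 36, 25.4 expected, Fisher's exact test, adjusted p = 0.0426), a call that ended against genes with as many peaks (adjusted p = 0.324). Contractile genes (28.3 expected, adjusted p = 0.0757) and regulators (21.2 expected, adjusted p = 0.195) did not pass Fisher's exact test, and with FLAG peaks within 3 kb of a TSS only both did (25 and 23 genes, adjusted p = 0.0470 and 0.00156). Against genes with as many peaks neither stood out (34.6 and 26.4 expected, permutation, adjusted p = 1 for both), and the counts within 3 kb were not tested against such genes. The remaining lists did not pass. Their counts were 14 of 14 immediate early targets (Fisher's exact test, adjusted p = 0.0658), 23 of 25 housekeeping (0.0658), 18 of 27 vascular channel and receptor, 26 of 37 extracellular matrix, 13 of 20 endothelial, 10 of 15 macrophage and leukocyte, and 16 of 22 osteogenic and chondrogenic genes. They were 7 of 10 pluripotency, 11 of 17 fibroblast and adventitial, 9 of 17 skeletal and cardiac muscle, 8 of 16 neural and neural crest, 18 of 21 H3K4 methylation machinery and 15 of 24 inflammatory genes.

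FLAG peaks sat largely on H3K4me2 peaks. Of all FLAG peaks, 69.0% (68.5 to 69.6) overlapped a Myocd-LSD1 H3K4me2 peak, 67.4% (66.9 to 68.0) a Myocd-LSD1NF peak and 65.1% (64.5 to 65.7) a control peak; 60.7% overlapped all 3 lists and 26.5% none. Shifted positions left 1.97%, 1.96% and 1.83% (one-sided permutation p = 0.001 for each, the smallest 1000 shifts can give). Seen from the mark, 42.0% of Myocd-LSD1 H3K4me2 peaks carried a FLAG peak, 50.2% at promoters and 35.4% elsewhere. No FLAG library from cells without the tag was analysed here, so background cutting at open chromatin was not measured.

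Counted over all sites, FLAG was found less often at sites lower in Myocd-LSD1 than at sites higher in it. A FLAG peak overlapped 22.7% of lower sites (21 to 24.5) and 32.5% of higher sites (30.8 to 34.2; odds ratio 0.612, two-sided Fisher's exact test over sites, p = 1.13e-14). The Myocd TSS site and both Cnn1 sites had no FLAG peak, though the Myocd site just upstream did; FLAG lay on the Acta2 TSS site and on lower sites of Itga8, Ppp1r14a, Lmod1, Myl9, Smad3 and Mkl2. The difference held at promoters (20.6% against 28.8%, Fisher's exact p = 4.35e-04) and away from them (23.3% against 35.3%, p = 1.92e-14), splits chosen after seeing the data. Within 10 strata of Myocd-LSD1 concentration, of which 8 were used, the odds ratio turned to 1.91 (95% interval 1.63 to 2.25). Within 10 strata of Myocd-LSD1NF concentration, of which 7 were used, it was 0.302 (0.258 to 0.353). These strata were also chosen after seeing the data. Counted over Myocd-LSD1 peaks, FLAG lay on 37.7% of peaks at lower sites, 33.0% at higher sites and 42.9% with no differential site. Counted over Myocd-LSD1NF peaks, FLAG lay on 23.0%, 44.8% and 41.6% of them. The order thus depended on the line whose peaks were counted.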

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

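Peaks on the mitochondrial genome were counted in the list overlaps and promoter shares, but no comparison looked at them on their own. They numbered 7 in the control, 7 in the Myocd-LSD1 and 7 in the Myocd-LSD1NF H3K4me2 list and 9 in the FLAG list. Their highest fold enrichment was 2.45, 2.50, 2.44 and 2.46 in these lists, and mitochondrial DNA carries no histones. Tests in the next paragraphs were chosen after the result was seen. For the direction tests against matched genes and the chromosome test, only the prediction was written before that test was run.

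FLAG was rarer at sites lower in Myocd-LSD1 than at higher ones. Within promoter sites and other sites taken apart the odds ratio stayed at 0.58 (0.510 to 0.660), and within 10 strata of mean concentration at 0.657 (0.575 to 0.751). Neither this coarse split by position nor the mean concentration of both lines removed the difference. Within 10 strata of Myocd-LSD1 concentration, of which 8 were used, the odds ratio turned to 1.91 (1.63 to 2.25). A FLAG signal that followed only how much H3K4me2 those cells carry would give an odds ratio near 1 there, so that level alone does not account for 1.91. Whether FLAG follows it in part, through open chromatin or through binding, stays open. Matching on Myocd-LSD1NF concentration, with 7 strata used, gave 0.302 (0.258 to 0.353), which shows how far matching on 1 line drives the answer. Removal of the mark at bound sites, the change the design asks about, stays open and untested, since no FLAG library from untagged cells was analysed here.

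SMC and matrix genes had lower sites, and osteogenic and chondrogenic genes higher sites, more often than other genes. Genes with many peaks have more chances of a site: against such genes the p was 0.0968 for contractile genes, 0.142 for regulators and 0.240 for matrix genes, so peak number could account for those counts, and 6.00e-04 for osteogenic and chondrogenic genes, which argues against it. With lower sites within 3 kb of a TSS only, contractile genes (6, 0.978 expected) and matrix genes (5, 0.880 expected) still passed Fisher's exact test (adjusted p = 0.00445 and 0.0117). Those counts were not tested against genes with as many peaks. Peak number leaves the direction open, and against matched genes with sites the share of lower sites had a permutation p = 0.00420 for contractile genes (82.6% against 44.9%) and 0.0388 for osteogenic and chondrogenic genes (11.1% against 41.8%). For regulators that p was 0.0490 (70.8% against 47.4%), too close to the threshold for 10000 draws to decide. These direction p-values are not adjusted over the 17 lists. They cover lists whose sites had already passed the direction test in the same data, so they are no independent support for the directions. The fusion's activity and a difference between the cell lines that is unrelated to it both stay open, as untested biological explanations.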

How the results depend on the processing

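Among 132 alternatives over 38 results, no result that passed its test passed it in the other direction, and 82 stayed on their side of the threshold or within the range set for them. The strata of concentration are not counted among these alternatives. There the FLAG contrast did turn, from an odds ratio of 0.612 over all sites to 1.91 (1.63 to 2.25) within strata of Myocd-LSD1 concentration. Without passing, contractile genes with a higher site went from below to above expectation with sites within 3 kb of a TSS (3 against 2.51), and regulators with a FLAG peak from above to below it against genes with as many peaks (26 against 26.4). Alternatives for the site directions, the control peak and promoter contrasts and the promoter, distal and control splits of the FLAG contrast, the promoter genes by the authors' annotation and the FLAG promoter share without the 50 highest H3K4me2 peaks were chosen after seeing the data. Promoter shares of the control, Myocd-LSD1, Myocd-LSD1NF and FLAG lists were 37.4%, 36.1%, 34.3% and 34.4% within 1 kb of a TSS, 63.0%, 62.5%, 60.1% and 53.0% in the top 50% of each list by q-value, and 56.8%, 56.1%, 54.0% and 47.4% of covered bases. Overlaps, in the order control on Myocd-LSD1, control on Myocd-LSD1NF, Myocd-LSD1 on control, Myocd-LSD1 on Myocd-LSD1NF, Myocd-LSD1NF on control and Myocd-LSD1NF on Myocd-LSD1, were 77.7%, 79.6%, 75.7%, 77.4%, 77.1% and 76.9% with at least 50% of either peak, 65.9%, 67.6%, 66.3%, 68.9%, 67.5% and 68.4% with 50% of both, and 95.8%, 95.6%, 96.2%, 95%, 97.9% and 96.7% for the top 50% of the list. FLAG on control, Myocd-LSD1 and Myocd-LSD1NF peaks gave 61.3%, 66.5% and 64.9% with at least 50% of the FLAG peak, 82.5%, 85.3% and 84.6% for its top 50%, and 67.9%, 71.2% and 69.5% within 1 kb. Lower sites numbered 1293 at an FDR of 0.01. The control peak contrast fell to 2.05 percentage points (Fisher's exact p = 0.147) with the top 50% of the control list. Against genes matched on peak number (permutation) the calls for the 12 contractile, 10 regulator and 10 matrix genes with a lower site (adjusted p = 0.573, 0.573 and 0.799) and the 33 cell cycle genes with a FLAG peak (0.324) ended, as did that for regulators with sites within 3 kb of a TSS only (3 genes, adjusted p = 0.141). FLAG peaks within 3 kb of a TSS brought contractile genes (25, Fisher's exact test, adjusted p = 0.0470) and regulators (23, adjusted p = 0.00156) past the threshold. The share of regulator sites that were lower, 70.8%, no longer passed at an FDR of 0.01 (60%, Fisher's exact p = 0.107) or for log2 differences of at least 1 (64.7%, p = 0.0836). Beyond what fewer or stronger peaks and sites entail, the cause was not tested. No paired analysis was possible because the files hold no values per sample, and leaving out each replicate and the replicate block were not run for the same reason. Unknown depth limits each statement that a peak is absent.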

Other observations

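HOX clusters leaned in different directions, a pattern noticed in the data and not tested. In the authors' deposited table all sites of the HOXB genes were higher in Myocd-LSD1: Hoxb8 (4.08 and 3.78), Hoxb7 (3.26), Hoxb6 (0.63), Hoxb2 (0.68) and Hoxb3, which was at the lowest Myocd-LSD1NF value. All sites of the HOXC genes were lower in the authors' deposited table: Hoxc5 (-4.21), Hoxc6 (-0.92 to -1.93), Hoxc8 (-1.58) and Hoxc4, which was at the lowest Myocd-LSD1 value. In the HOXD cluster Hoxd10 (2.63) and Hoxd13 (1.14) were higher and Hoxd4 (-1.28 and -1.24) and Hoxd1 (-5.34) lower in the authors' deposited table. HOX genes record the body position of a cell, and neighbouring genes of a cluster are not independent.

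Vascular signalling genes also had sites in both directions, though their list did not pass. Rgs4, a regulator of G protein signalling, was lower at its TSS (-5.31), as were Gucy1b3 (-3.20), a subunit of the nitric oxide receptor, and Kcnj8 (-2.55) in the authors' deposited table. Sites near Cacna1c, the L-type calcium channel gene, (-3.33 and -1.34) and upstream of Pde3a (-1.63) were also lower in the authors' deposited table. The cation channel gene Trpc6 (3.69) and the adrenergic receptor gene Adra1a (2.09) were higher at their TSS or within 3 kb of it in the authors' deposited table. Matrix genes with higher sites in the authors' deposited table included Mmp2 (2.64), Col6a1 (2.06), Loxl2 (2.05) and Col6a2 (1.74 and 1.34), with Spp1 and Col6a3 at the lowest Myocd-LSD1NF value.

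Sites came in runs along the chromosome. Neighbouring sites within 10 kb had the same direction in 87.9% of 479 pairs, those 10 to 100 kb apart in 68.1% of 1431 pairs and those more than 1 Mb apart in 53.1% of 697 pairs, against 51.3% from the shares of the directions. Of 12 genes with at least 6 sites, 8 had only higher sites (Lmo7 12, Arhgap32 8, Nhsl1 7, and Efna5, Fbxl17, Frem1, LOC108352378 and Tgfb2 6 each), 0 only lower ones, and Foxp1, Meis1, Bmpr1b and Tns1 had both. At Lmo7 they spread over 163 kb of chromosome 15 (86263531 to 86426813), and 7 of the 12 overlapped a control peak.

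Chromosomes differed in the share of sites higher in Myocd-LSD1, from 42.5% on chromosome 6 to 73.9% on chromosome 15 (permutation with sites within 100 kb moved together, p = 0.0001, the smallest 10000 permutations can give). A test whose prediction was written before it was run asked whether different numbers of whole chromosomes in the lines account for this. It took the 2947 sites with a log2 difference of at least 2 in size. Among these, chromosomes still differed (permutation p = 0.0001, again the smallest possible). That bound was poorly chosen, since a constant shift along a chromosome carries sites past it too, so copy number and regional change cannot be told apart here. No read depth per chromosome was analysed here.

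Among the 50 highest FLAG peaks, 35 were distal intergenic, 6 lay within 3 kb of a TSS and 33 overlapped a peak in all 3 H3K4me2 lists. Of them, 4 overlapped a top peak of all 3 H3K4me2 lists, against 18 of 26323 other FLAG peaks (Fisher's exact p = 8.15e-08). This comparison was chosen after seeing the data.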
